A study of Mus musculus with 30 samples.

How the data were processed

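Uterine RNA of 21-day-old female mice was measured on 30 Affymetrix whole-transcript arrays, 3 for each of 10 groups of genotype, treatment and time. Total RNA was extracted with Trizol and RNeasy, and 300 ng was amplified and biotin-labelled with the WT Plus kit. The KO mice are labelled as lacking exon 3 of the gene of estrogen receptor alpha. The probe set of Esr1 may lie outside that exon, so its level is a limited check of the genotype.

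The values were used as deposited: the authors gave log2 values for 72688 probe sets. The software, background correction, normalization, summarization and array build are not given in the sources used here, and no coordinates are printed. On 23 arrays some probe sets lay at 19.93, the highest deposited value. An annotation listed 32750 probe sets, 30604 with 1 symbol, which were kept, and 2146 with several, which were tested apart together with the 39938 not listed. After 827 symbols were updated through Entrez, 30142 genes were tested, and for 355 genes with several probe sets the one of highest mean was used. Genes of close sequence, as among Klk1 and its relatives, Sprr2, Speer4 and the histones, may share probes, so a change is not assigned to 1 member with certainty.

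The groups, the 21 comparisons, the gene lists, the thresholds and the alternative settings were fixed from the labels before the data were examined. Group means over all 30 arrays were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, 20 residual degrees of freedom, prior degrees of freedom 3.66), and tables were handled with data.table (version 1.17.8). P-values of limma were adjusted by the Benjamini-Hochberg method within each comparison, and genes at adjusted p < 0.05 were called; a further limit was 2-fold. Genotype interactions were tested as the change in KO minus the change in WT. The 23 gene lists and 17 marker lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Lists were also adjusted over their members alone. Planned members without a probe set of their own were left out, and older names were matched only where no other gene bears them as its current symbol. This matching was corrected after the results were seen, which removed 5 wrongly matched genes from 4 lists. Limma tests are moderated t-tests and assume normal errors; with 3 arrays against 3 no permutation test reaches a share under 0.05, so the splits of the arrays are given as counts.

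A floor for each array was set at the 95th percentile of 1225 olfactory receptor genes, 5.69 to 6.57, and folds are given as "at least" where the dimmer group lay at it. These bounds come from group means, and the log2 values beside them rest on a value within background, so their size and rank are uncertain. Medians of the arrays ran from 6.17 to 6.47, the mean correlation with arrays of the same group from 0.975 to 0.994, and array weights from 0.166 to 3.66.

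Named genes were picked by a rule: for each comparison the 8 largest rises and the 8 largest falls at adjusted p < 0.05, at least 2-fold and with no overlap between the replicates compared. Predicted genes, clones, microRNAs and other small RNAs, olfactory and vomeronasal receptors and antibody or T cell receptor segments were left out. For interactions the overlap condition was dropped. For the contrasts between treatments and between genotypes under treatment, the first 4 in each direction are printed. Up to 4 members of largest change per list, and Esr1, Pgr, Igf1, Igf1r, Esr2 and Greb1, were added.

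Alternatives were arrays centred on their medians, quantile normalization, removal of dim genes (18245 kept, 11897 removed), the mean of all probe sets of a gene, only the compared groups in the fit, a trended robust prior, array weights, the replicate number as a block, and each array left out in turn. After the data had been seen, a fit without the 2 arrays of lowest weight (WT vehicle replicate 1 and KO E2 24 h replicate 2) was added. The fit was tested on simulated data with 50 changed genes per size. In the contrast of E2 at 2 h with vehicle in WT it recovered 98% of changes of log2 2 and 56% of log2 1 with 2 false calls, and in the interaction for IGF1 at 2 h 94% and 46% with 9.

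The vehicle was saline and was sampled at 24 h alone, while IGF1 was given in PBS, so contrasts with vehicle at 2 h also hold time after injection. Contrasts between treatments at 2 h avoid it, and contrasts between genotypes cancel it only if it acts alike in both. At 24 h IGF1 had been given 3 times, the last at 16 h, and E2 and saline once, so IGF1 contrasts with E2 or vehicle within a genotype also hold the number and timing of injections. Raw array images and raw intensities were not analysed here.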

Results

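Gene expression was measured in the uterus of prepubertal female mice, 21 days old, on 30 arrays. The mice were wild type (WT) or carried a deletion in the gene of estrogen receptor alpha (knockout, KO). They received saline, 17β-estradiol (E2, 250 ng in 100 ul saline) or insulin-like growth factor 1 (IGF1, 50 ug in PBS). E2 samples were taken at 2 h and 24 h, IGF1 samples at 2 h after 1 injection and at 24 h after 3 injections, and saline samples only at 24 h. Each of the 10 groups had 3 arrays, a number that limits precision. The labels do not say whether the replicates are separate animals, so the p-values measure only the spread between these samples. Changes are log2 differences ± standard error (SE) between groups of n = 3, a gene was called at limma adjusted p < 0.05, and 30142 genes were tested.

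The first question was how untreated KO and WT uteri differed. Esr1, the gene of estrogen receptor alpha, was at 10.26 in KO and 12.30 in WT, a change of -2.04 ± 0.19. Genes higher in KO included Slc13a5, a citrate transporter, by 3.84 ± 0.51 (14.4-fold, adjusted p = 8.39e-05), Coch by 3.49 ± 0.46 and Tfcp2l1, an epithelial transcription factor, by 3.46 ± 0.42. They also included Efhd1 (3.39 ± 0.31), the prostaglandin D synthase gene Hpgds (3.29 ± 0.43), the secreted hormone gene Stc1 (3.26 ± 0.48), the cardiac troponin gene Tnnt2 (3.12 ± 0.57) and the chemokine gene Cxcl17 (3.07 ± 0.50). Genes lower in KO included the chemokine gene Cxcl15 (-4.23 ± 0.65), the cystine transporter gene Slc7a11 (-3.80 ± 0.41), the relaxin receptor gene Rxfp1 (-3.62 ± 0.35) and Egfl6 (-3.18 ± 0.67). Wfdc15b (-2.93 ± 0.67), Jchain of secreted antibodies (-2.89 ± 0.53), the steroid-metabolizing Akr1c14 (-2.88 ± 0.29) and the plasminogen activator gene Plat (-2.73 ± 0.44) were lower as well. Igf1 itself was lower in KO by -1.03 ± 0.28 and the estrogen-induced gene Greb1 by -0.81 ± 0.14 (at least 1.28-fold), while the progesterone receptor gene Pgr (0.03) and Igf1r (0.68) were not called.

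Of 14 markers of uterine epithelium, 5 were called higher in KO and none lower, for example Krt7 by 1.60 ± 0.28 and Cldn3 by 1.54 ± 0.35 (camera adjusted p = 9.63e-10, adjusted p = 0.389 with an estimated correlation). Adjusted over the list alone, 10 were higher and 1 lower. Of 30 collagens and matrix genes, 8 were called lower and none higher, such as Thbs1 (-2.21 ± 0.44) and the matrix metalloproteinase genes Mmp2 (-1.90 ± 0.47) and Mmp14 (-1.83 ± 0.37); the list gave adjusted p = 5.89e-06, and adjusted p = 0.637 with an estimated correlation. Markers of other cells were lower as lists with no member called: uterine stroma with a median of -0.56 (adjusted p = 0.00933), macrophages -0.53 (adjusted p = 0.00738) and endothelium -0.30 (adjusted p = 0.0135), each at adjusted p = 0.966 with an estimated correlation. A different mix of cells in the samples is therefore not excluded. In all, 879 genes were called, 486 higher and 393 lower in KO, and of these 220 and 178 differed at least 2-fold. The count was 470 without KO vehicle replicate 2, 567 without WT vehicle replicate 3, 211 with only the compared groups in the fit and 2444 with array weights. Xist, the RNA that coats the inactive X chromosome, was at 10.16 on WT vehicle replicate 1 against 17.01 to 18.12 on the other arrays.

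The next question was which genes E2 changed in the WT uterus after 2 h. Klk1, a tissue kallikrein protease, rose by 9.30 ± 0.36 (at least 425-fold, adjusted p = 2.22e-15), and its relative Klk1b5 by 6.09 ± 0.22 (at least 33.4-fold). Mad2l1, a spindle checkpoint gene, rose by 7.40 ± 0.27 (169-fold) and the glycosyltransferase gene B4galt5 by 6.33 ± 0.35 (80.5-fold). The stress-induced Gadd45g rose by 6.27 ± 0.21 (at least 67.2-fold), the placental growth factor gene Pgf by 6.22 ± 0.16, the aggrecan-cleaving protease gene Adamts4 by 5.81 ± 0.36 (at least 26.9-fold) and the kinase gene Plk2 by 5.59 ± 0.25. The largest falls were in Rspo3, an activator of Wnt signalling (-4.76 ± 0.61, adjusted p = 3.25e-06), Rgs2, a brake on G protein signals (-4.62 ± 0.48), the transcription factor gene Sox4 (-3.69 ± 0.30) and the hedgehog receptor gene Ptch1 (-3.55 ± 0.47). Stc1 (-3.06 ± 0.48), the clock output gene Dbp (-3.04 ± 0.24), Lrrc17 (-3.04 ± 0.45) and Rbm24 (-3.02 ± 0.46) also fell. Dbp was lower with IGF1 at 2 h in WT too (-2.02), so its fall is not particular to E2. Among receptor and reporter genes Greb1 rose by 4.83 ± 0.14, the corepressor gene Nrip1 by 3.65 ± 0.13, Pgr by 2.67 ± 0.33 and Igf1 by 2.49 ± 0.28, while Esr1 fell by 0.81 ± 0.19. Igf1r (-0.29) was not called, and Esr2, the gene of estrogen receptor beta, lay at background, so its change was not assessed.

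Of 25 immediate early transcription factors, 19 rose and none fell at 2 h of E2 in WT, with Ier3 at 4.02 ± 0.31, Fos at 3.94 ± 0.21 (at least 8.26-fold) and Nr4a1 at 3.94 ± 0.28 (camera adjusted p = 3.31e-23). Of 29 genes of the early uterine estrogen response, 18 rose and 3 fell, among them Rasd1 (5.58 ± 0.51), Ccn1 (5.57 ± 0.40) and the cell cycle inhibitor gene Cdkn1a (4.95 ± 0.50), with adjusted p = 6.02e-20. Of 29 genes of ribosome biogenesis, 25 rose, such as Ddx21 by 3.10 ± 0.42 and Nop58 by 2.29 ± 0.29 (adjusted p = 1.88e-22, adjusted p = 0.0651 with an estimated correlation). Of 19 MAPK pathway feedback genes, 10 rose and 2 fell, Errfi1 by 4.09 ± 0.33 and Spry4 by 3.70 ± 0.65 among the rises (adjusted p = 1.13e-05, adjusted p = 0.0562 with an estimated correlation). This list holds growth factor genes as well as genes that damp growth factor signals. Of 22 ER chaperones and unfolded protein response genes, 12 rose, Hspa5 by 2.30 ± 0.29 for example (adjusted p = 4.5e-07, adjusted p = 0.247 with an estimated correlation).

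Of 37 Wnt signalling genes, 13 fell and 2 rose in the same comparison, Dkk2 falling by 2.35 ± 0.54 and Axin2 rising by 2.06 ± 0.19 (adjusted p = 0.0206, adjusted p = 0.0769 with an estimated correlation). Of 12 uterine stroma markers, 6 fell, such as Col3a1 (-2.41 ± 0.30) (adjusted p = 0.000173, adjusted p = 0.247 with an estimated correlation). Of 21 interferon response genes, 8 fell and 1 rose, Ifit3b by -2.23 ± 0.42 and Ifit2 by -2.02 ± 0.36 (adjusted p = 0.0168, adjusted p = 0.979 with an estimated correlation). Of 26 angiogenic and vasoactive genes, 9 rose, Vegfa by 4.38 ± 0.46 for example, and 8 fell (camera adjusted p = 0.0691). Of 28 mitosis genes only Mad2l1 and Tpx2 (0.83 ± 0.23) rose (adjusted p = 0.221). Adjusted over each list alone, 20 immediate early, 21 early estrogen, 27 ribosome biogenesis, 10 MAPK feedback and 14 ER genes were higher, and 14 Wnt, 9 stroma and 9 interferon genes lower. In all 5731 genes were called, 2965 higher and 2766 lower, with 1158 and 744 at least 2-fold. With array weights 9266 were called, and with the arrays centred 66.3% of the calls were higher against 51.7%. The control uteri were taken only at 24 h, so this contrast, like every 2 h contrast with vehicle, also holds the difference in time after injection.

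After 24 h of E2 the question was which genes had changed in WT. Sprr2f, a small proline-rich protein of epithelial surfaces, rose by 10.33 ± 1.55 (adjusted p = 1.74e-05), Sprr2b by 7.99 ± 1.24 and Sprr1a by 7.61 ± 1.12 (at least 129-fold). Klk1 was still higher by 6.56 ± 0.36 (at least 63.2-fold), with rises in the adhesion receptor gene Adgrg7 (5.99 ± 0.56, at least 50.2-fold), the mitotic ubiquitin-conjugating enzyme gene Ube2c (5.90 ± 0.53, 59.7-fold), the linker histone gene H1f5 (5.84 ± 0.60) and Clca1 (5.77 ± 0.68). The largest falls were Pamr1 (-3.88 ± 0.53), the TGF-beta-induced matrix gene Tgfbi (-3.83 ± 0.51), the methyltransferase gene Inmt (-3.73 ± 0.96) and the IGF-binding protein gene Igfbp3 (-3.68 ± 0.49). Speer8-ps1 (-3.46 ± 0.60), Galnt15 (-3.18 ± 0.64), the leptin receptor gene Lepr (-3.17 ± 0.46) and Apod (-3.16 ± 0.74) fell too. Igf1 rose by 1.62 ± 0.28 (adjusted p = 0.000112), Greb1 rose by 0.52 ± 0.14, and Igf1r fell by 1.78 ± 0.33 (adjusted p = 0.000237). Pgr was at 0.79 ± 0.33 (adjusted p = 0.0768) and Esr1 at -0.29, neither called.

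All 28 mitosis and G2/M genes rose at 24 h of E2 in WT, Ccnb2 by 5.48 ± 0.44, the topoisomerase gene Top2a by 4.70 ± 0.57 (adjusted p = 8.97e-35, adjusted p = 0.0567 with an estimated correlation). Of 29 genes of DNA replication and G1/S, 28 rose, Rrm1 by 3.62 ± 0.27 and E2f8 by 3.15 ± 0.21, at least 5.39-fold (adjusted p = 3.74e-33). All 18 genes of cholesterol synthesis rose, such as Fdps by 5.18 ± 0.36 and Idi1 by 4.12 ± 0.43 (adjusted p = 6.18e-22, adjusted p = 0.0567 with an estimated correlation). Of 24 late secretory and epithelial estrogen genes, 18 rose, among them Muc1, a surface mucin, by 5.05 ± 0.42 (adjusted p = 2.96e-12, adjusted p = 0.0763 with an estimated correlation). Of 14 epithelium markers, 11 rose, Elf3 by 4.15 ± 0.38 and Krt8 by 4.06 ± 0.39 (adjusted p = 1.53e-10, adjusted p = 0.0763 with an estimated correlation).

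Ribosome biogenesis genes rose in 27 of 29 cases in this comparison, Nhp2 by 3.06 ± 0.26 (adjusted p = 1.96e-19, adjusted p = 0.0763 with an estimated correlation). Genes of the list for mitochondrial oxidative phosphorylation rose in 22 of 24 cases, Cs by 3.35 ± 0.52 and Cox5a by 3.08 ± 0.45 (adjusted p = 1.31e-14, adjusted p = 0.0966 with an estimated correlation). Cs, a member of this list, is the gene of citrate synthase, an enzyme of the citric acid cycle. Of 22 ER chaperones, 17 rose, Calr by 2.68 ± 0.29 (adjusted p = 1.55e-11, adjusted p = 0.0812 with an estimated correlation). Of 30 collagens and matrix genes, 17 rose and 3 fell, Col6a2 by 4.14 ± 0.24 and Col1a1 by 3.34 ± 0.22 (adjusted p = 8.07e-07, adjusted p = 0.161 with an estimated correlation). Of 19 genes of glycolysis and glucose uptake, 10 rose and 1 fell, Pgk1 by 3.09 ± 0.33 (adjusted p = 0.000498, adjusted p = 0.36 with an estimated correlation). Of 24 FoxO target genes, 7 fell and 1 rose, Txnip by -2.31 ± 0.44 (adjusted p = 0.0332, adjusted p = 0.76 with an estimated correlation). Of 37 Wnt signalling genes, 11 fell and 3 rose, Rspo3 by -1.66 ± 0.61 (adjusted p = 0.0467, adjusted p = 0.107 with an estimated correlation). With adjustment over each list alone, the rises were 28 of mitosis, 28 of replication, 18 of cholesterol synthesis, 19 late estrogen and 12 epithelial genes. A total of 9065 genes were called, 5056 higher and 4009 lower, with 2391 and 816 at least 2-fold. The median over all genes was -0.10, and with the arrays centred the share of higher calls went from 55.8% to 69.6%.

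**Figure D1:**
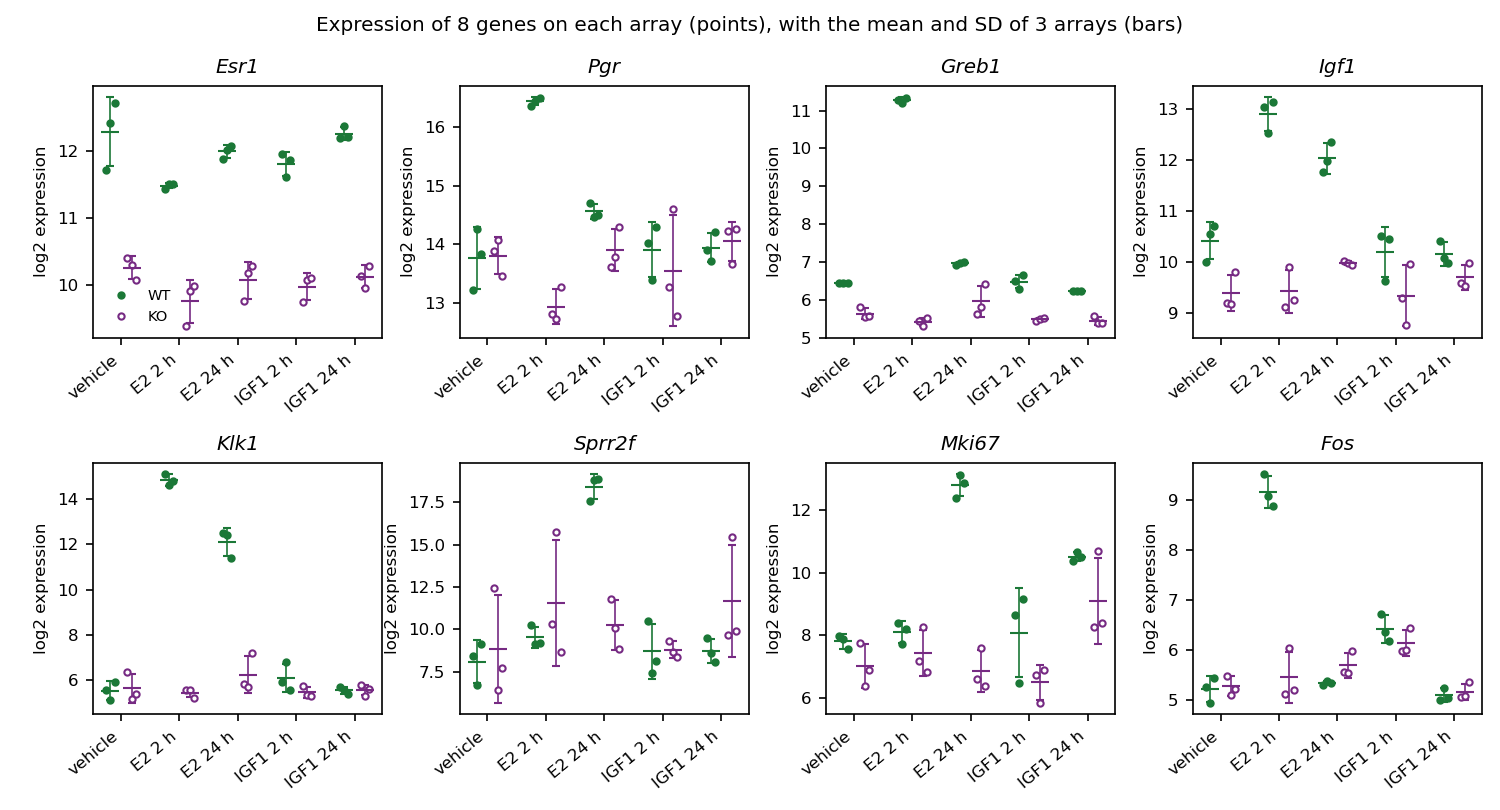
Values (log2 intensity) of Esr1, Pgr, Greb1, Igf1, Klk1, Sprr2f, Mki67 and Fos on each array, by genotype and treatment; each point is 1 array. Klk1 rose by 9.30 at 2 h and Sprr2f by 10.33 at 24 h of E2 in WT.

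For IGF1 in WT at 2 h, the question was which genes changed after 1 injection. The mesenchymal surface gene Cd248 rose by 4.62 ± 0.54 (24.6-fold, adjusted p = 5.82e-06), the cytokine receptor gene Tnfrsf12a by 4.48 ± 0.57, the matricellular gene Ccn1 by 3.99 ± 0.40 and the heat shock gene Hsph1 by 3.95 ± 0.30. Spry4 rose by 3.91 ± 0.65, the transcription factor gene Egr1 by 3.54 ± 0.57, the fatty acid synthase gene Fasn by 3.51 ± 1.04 and Cdkn1a by 3.49 ± 0.50. Fbxo32, a ubiquitin ligase gene turned on by FoxO factors, fell by 5.54 ± 0.81 (46.6-fold, adjusted p = 4.51e-05). Klhl24 (-3.71 ± 0.63), Fam214a (-3.05 ± 0.39), the sestrin gene Sesn1 (-2.93 ± 0.52), Zc3h6 (-2.86 ± 0.27), Arrdc3 (-2.75 ± 0.50), Trp53inp1 (-2.70 ± 0.52) and Cir1 (-2.70 ± 0.45) fell as well. The estrogen-induced genes Pgr (0.14) and Greb1 (0.03) were not called, nor were Igf1 (-0.22), Esr1 (-0.48 ± 0.19) and Igf1r (-0.82 ± 0.33, adjusted p = 0.098).

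Of the immediate early genes, 17 of 25 rose with IGF1 at 2 h in WT, Nr4a1 by 3.36 ± 0.28 and Srf by 3.13 ± 0.28 (adjusted p = 9.92e-17). MAPK pathway feedback genes rose in 10 of 19 cases, Dusp6 by 3.44 ± 0.39 (adjusted p = 2.52e-06), and early estrogen response genes in 10 of 29, Slc7a5 by 3.23 ± 0.60 and Vegfa by 3.17 ± 0.46 (adjusted p = 3.35e-05). Ribosome biogenesis genes rose in 25 of 29 cases, Ddx21 by 3.09 ± 0.42 (adjusted p = 2.33e-25). ER chaperones rose in 16 of 22, Atf4 by 2.38 ± 0.37 and Hspa5 by 2.31 ± 0.29 (adjusted p = 1.96e-13, adjusted p = 0.0627 with an estimated correlation). Cholesterol synthesis genes rose in 12 of 18, Cyp51 by 2.59 ± 0.38 (adjusted p = 8.57e-10, adjusted p = 0.228 with an estimated correlation). Of 24 FoxO target genes, 11 fell and 3 rose, Sesn3 by -2.64 ± 0.44 (adjusted p = 0.00141, adjusted p = 0.617 with an estimated correlation). Genes of oxidative phosphorylation rose in 6 of 24 cases, Cycs by 2.82 ± 0.58 (adjusted p = 2.52e-06, adjusted p = 0.593 with an estimated correlation). Adjusted over each list alone, the higher genes were 17 immediate early, 11 MAPK feedback, 12 early estrogen, 27 ribosome biogenesis, 17 ER and 12 cholesterol genes, and 15 FoxO targets were lower. The comparison called 5178 genes, 2875 higher and 2303 lower, with 979 and 570 at least 2-fold. The count was 3338 with only the compared groups in the fit and 8595 with array weights, and centred arrays moved the higher share from 55.5% to 70.8%.

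After 3 injections of IGF1 over 24 h in WT, the question was what remained changed. Igfbp5, an IGF-binding protein gene, rose by 4.12 ± 0.55 (17.3-fold, adjusted p = 0.000395). Of 32 linker and core histone genes, a family chosen after the results were seen, 7 were called higher and 1 lower, with rises in H1f5 by 3.57 ± 0.60, Hist1h2aj by 3.12 ± 0.55 and H2ac10 by 2.82 ± 0.44. The galectin gene Lgals1 (2.83 ± 0.53), Mki67 (2.72 ± 0.59), the retinoid-binding gene Crabp1 (2.67 ± 0.37) and the topoisomerase gene Top2a (2.64 ± 0.57) rose too. Lepr fell by 2.52 ± 0.46, Neto2 by 2.38 ± 0.28, Galnt15 by 2.26 ± 0.64, Cdr1 by 2.18 ± 0.60 and Pamr1 by 2.09 ± 0.53. H1f2 (-1.67 ± 0.45), the matrix gene Thbs1 (-1.65 ± 0.44) and the dystrophin gene Dmd (-1.60 ± 0.27) fell less. Of the receptor genes none was called, Igf1r being at -0.78 (adjusted p = 0.204).

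Mitosis genes rose in 19 of 28 cases in this comparison, Ube2c by 2.24 ± 0.53 and Ccnb2 by 2.15 ± 0.44 (adjusted p = 3.59e-24, adjusted p = 0.142 with an estimated correlation). DNA replication genes rose in 15 of 29, Mcm3 by 1.26 ± 0.22 (adjusted p = 1.26e-23, adjusted p = 0.0672 with an estimated correlation). Genes of the oxidative phosphorylation list rose in 12 of 24, the citrate synthase gene Cs by 1.83 ± 0.52 (adjusted p = 3.25e-17, adjusted p = 0.142 with an estimated correlation). Cholesterol synthesis genes rose in 6 of 18, Idi1 by 1.77 ± 0.43 (adjusted p = 1.56e-12, adjusted p = 0.157 with an estimated correlation). ER chaperones rose in 7 of 22, Calr by 1.64 ± 0.29 (adjusted p = 1.59e-11, adjusted p = 0.142 with an estimated correlation). Of 30 collagens and matrix genes, 10 rose and 2 fell, Fn1 by 2.26 ± 0.48 and Col1a1 by 1.99 ± 0.22 (adjusted p = 1.65e-08, adjusted p = 0.157 with an estimated correlation). When each list was adjusted alone, 24 mitosis, 24 replication, 18 oxidative phosphorylation, 14 cholesterol, 14 ER and 13 matrix genes were higher. The 1291 genes called were 1001 higher and 290 lower, with 495 and 59 at least 2-fold. The count was 278 without WT IGF1 24 h replicate 1, 429 without replicate 3, 547 without WT vehicle replicate 1, 136 with only the compared groups in the fit, 728 without the arrays of lowest weight and 3946 with array weights. Quantile normalization moved the higher share from 77.5% to 66.8%.

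In KO uteri the first question was what E2 changed at 2 h. Acod1, an itaconate-producing enzyme gene, rose by 4.03 ± 0.64 (adjusted p = 0.00459) from background to 8.56, 11.68 and 7.32 on the 3 arrays, and by 2.78 without replicate 2. Also higher were the endocytic receptor gene Lrp2 by 3.68 ± 0.43, Zbtb16, a transcription factor gene induced by glucocorticoids, by 3.64 ± 0.60 and Slc25a48 by 3.42 ± 0.47. The histamine-forming Hdc rose by 3.33 ± 0.47, Plet1 by 2.76 ± 0.38, the sulfotransferase gene Sult1d1 by 2.63 ± 0.44 and the zinc transporter gene Slc39a4 by 2.31 ± 0.38. Hpgds fell by 3.34 ± 0.43 (10.1-fold), Stc1 by 2.49 ± 0.48, Akr1c19 by 1.76 ± 0.34, Fgf9 by 1.17 ± 0.20, the Wnt secretion gene Wls by 1.10 ± 0.21, Ccdc62 by 1.05 ± 0.17 and Akr1c13 by 1.02 ± 0.23. Pgr (-0.87 ± 0.33), Igf1 (0.04) were not called, and Greb1 lay at background in both groups.

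Of 20 genes of the progesterone and hedgehog axis, 4 rose with E2 at 2 h in KO, Acod1, Lrp2, Sult1d1 and Fkbp5 (1.24 ± 0.19), a steroid-induced chaperone gene, with adjusted p = 2.59e-06, and adjusted p = 0.074 with an estimated correlation. Of 24 FoxO target genes, Zbtb16 and Bcl6 (1.63 ± 0.36) rose (adjusted p = 1.4e-05, adjusted p = 0.345 with an estimated correlation). None of 25 immediate early genes was called (adjusted p = 0.0502). The lactoferrin gene Ltf of the late estrogen list was at 5.91 ± 1.40 and not called. No member of 12 macrophage markers (adjusted p = 3.4e-09, adjusted p = 0.234 with an estimated correlation) or 21 interferon response genes (adjusted p = 3.2e-11, adjusted p = 0.234 with an estimated correlation) was called, while 10 and 9 were higher when adjusted over the list alone. Adipocyte markers had the largest median of any list, 1.01, with none of 11 called (adjusted p = 3.44e-05, adjusted p = 0.345 with an estimated correlation). Adipoq ran from 8.22 to 11.54 over the KO vehicle arrays alone, so uneven amounts of fat tissue are not excluded. In all 110 genes were called, 78 higher and 32 lower, with 48 and 10 at least 2-fold. The count was 28 without KO vehicle replicate 1, 43 without KO vehicle replicate 2, 29 without KO E2 2 h replicate 2 and 332 without replicate 3. With only the compared groups in the fit it was 7, without the arrays of lowest weight 235, and centred arrays moved the higher share from 70.9% to 81.1%.

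At 24 h of E2 in KO, the question was whether any gene still differed from vehicle. Limma called 0 genes, with 3735 at unadjusted p < 0.05, 0 with array weights or a replicate block, 1 with centred arrays and 1 with quantile normalization. Of genes called at 24 h of E2 in WT, Sprr2f was at 1.42 ± 1.55, Fdps at -0.29 ± 0.36, Ccnb2 at -0.38 ± 0.44, with 1 group at background, Krt8 at -0.44 ± 0.39 and Igf1 at 0.59 ± 0.28, and none of these was called. No member of any list was called, although ER chaperones gave adjusted p = 0.000214 (adjusted p = 0.924 with an estimated correlation) and ribosome biogenesis adjusted p = 0.000261 (adjusted p = 0.924 with an estimated correlation). The count was 38 without KO E2 24 h replicate 3, 3 without replicate 1, 4 without KO vehicle replicate 1 and 2 without KO vehicle replicate 2.

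The test of the genotype difference asked whether E2 acted differently in KO and WT at 2 h, as KO change minus WT change. Genes with the most negative difference were Klk1 (-9.50 ± 0.51, adjusted p = 4.79e-12), Mad2l1 (-7.53 ± 0.39), Ccn1 (-6.34 ± 0.57), Klk1b5 (-6.30 ± 0.32), Gadd45g (-6.11 ± 0.30), Pgf (-5.91 ± 0.22), B4galt5 (-5.62 ± 0.50) and Adamts4 (-5.52 ± 0.50). The estrogen-induced genes Greb1 (-5.05 ± 0.19), Pgr (-3.54 ± 0.47), Nrip1 (-3.25 ± 0.19) and Igf1 (-2.45 ± 0.40) also differed. Positive differences were largest for the serpin gene Serpinb11 (5.43 ± 1.58), Rspo3 (4.83 ± 0.86), Rgs2 (4.71 ± 0.67), Acod1 (4.14 ± 0.91), the tight junction gene Cldn1 (3.71 ± 1.16), Sesn1 (3.69 ± 0.74), Sox4 (3.49 ± 0.42) and the antibody transporter gene Pigr (3.42 ± 1.07). For Acod1, Adamts4 and Klk1b5 3 of the 4 groups lay at background, for Klk1 and Greb1 2 and for Gadd45g 1, so the sizes and ranks of these differences are uncertain. Of 25 immediate early genes, 16 differed negatively (adjusted p = 2.56e-21), of 29 early estrogen genes 18 negatively and 3 positively (adjusted p = 9.91e-20), and of 19 MAPK feedback genes 8 negatively (adjusted p = 1.03e-06). Ribosome biogenesis genes differed negatively in 19 of 29 cases, Nop58 by -2.62 ± 0.41 (adjusted p = 2.56e-21, adjusted p = 0.0553 with an estimated correlation). Positive differences were called for 8 of 12 stroma markers, Hoxa11 by 2.57 ± 0.40 (adjusted p = 3.49e-08, adjusted p = 0.0553 with an estimated correlation), and 8 of 21 interferon genes, Xaf1 by 2.69 ± 0.46 (adjusted p = 2.86e-10, adjusted p = 0.289 with an estimated correlation). Adjusted over each list alone, 19 immediate early genes were negative and 15 interferon genes positive. In all 2412 genes were called, 1089 positive and 1323 negative, 4626 with array weights, and centring moved the positive share from 45.1% to 34.2%.

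At 24 h the same question gave the most negative differences for Sprr2f (-8.91 ± 2.19), Sprr2b (-8.07 ± 1.75), Sprr1a (-7.17 ± 1.58), Clca1 (-6.35 ± 0.96), Adgrg7 (-6.25 ± 0.79), H1f5 (-6.11 ± 0.84), Ube2c (-6.01 ± 0.75) and Klk1 (-5.95 ± 0.51). Positive differences were largest for Cdr1 (4.23 ± 0.85), Pamr1 (3.57 ± 0.74), Igfbp3 (3.55 ± 0.70), Tgfbi (3.22 ± 0.72), Apod (3.22 ± 1.04), Abi3bp (3.13 ± 0.49), Speer8-ps1 (3.08 ± 0.86) and the transporter gene Abca8a (3.03 ± 0.58). For Adgrg7 2 of the 4 groups, and for Klk1, H1f5 and Sprr1a 1, lay at background, which leaves the sizes of these differences uncertain. Igf1 (-1.03 ± 0.40, adjusted p = 0.0662) and Igf1r (1.23 ± 0.47, adjusted p = 0.0614) were not called. Mitosis genes differed negatively in 27 of 28 cases, Ccnb2 by -5.85 ± 0.63 (adjusted p = 5.25e-34, adjusted p = 0.0615 with an estimated correlation), and replication genes in 27 of 29, Rrm1 by -4.30 ± 0.38 (adjusted p = 3.61e-33). All 18 cholesterol synthesis genes did, Fdps by -5.47 ± 0.51 (adjusted p = 8.44e-22, adjusted p = 0.0615 with an estimated correlation), as did 10 of 14 epithelium markers, Krt8 by -4.50 ± 0.55 (adjusted p = 1.05e-10, adjusted p = 0.0711 with an estimated correlation). A total of 6672 genes were called, 3002 positive and 3670 negative. The count was 4046 with only the compared groups in the fit and 4061 without the arrays of lowest weight; the median over all genes was 0.19, and centring moved the positive share from 45.0% to 22.6%.

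**Figure D2:**
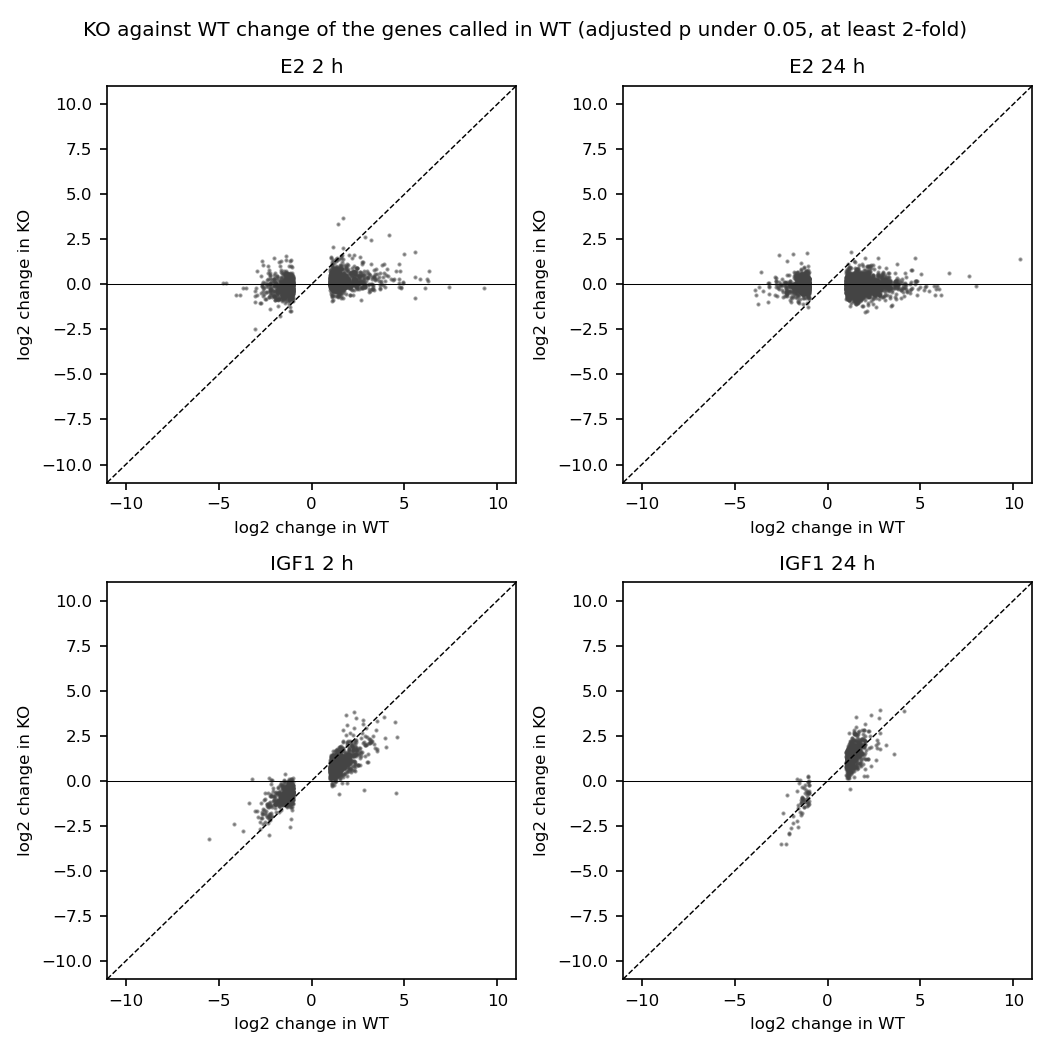
Log2 change in KO (vertical) against log2 change in WT (horizontal) for genes called at least 2-fold in WT, 1 panel per treatment and time; each point is 1 gene. The median of the genes higher in WT was 0.16 in KO for E2 at 2 h, -0.04 for E2 at 24 h, 0.87 for IGF1 at 2 h and 1.38 for IGF1 at 24 h.

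The question for IGF1 in KO at 2 h was which genes rose or fell. The chemokine gene Ccl12 rose by 3.82 ± 0.50 (14.2-fold, adjusted p = 0.000243), Spry4 by 3.52 ± 0.65, the matrix gene Thbs1 by 3.37 ± 0.44, Egr1 by 3.29 ± 0.57 and Tnfrsf12a by 3.27 ± 0.57. Slc25a48 rose by 3.17 ± 0.47, the fibronectin receptor gene Itga5 by 2.92 ± 0.42 and Hdc by 2.91 ± 0.47. Hpgds fell by 3.16 ± 0.43, Speer8-ps1 by 2.99 ± 0.60, Arrdc3 by 2.30 ± 0.50, Speer4e by 2.18 ± 0.49, Zc3h6 by 2.00 ± 0.27, Speer4d by 1.93 ± 0.40, Sesn3 by 1.75 ± 0.44 and the chemokine receptor gene Cxcr4 by 1.74 ± 0.46. Of 25 immediate early genes, 15 rose, Zfp36 by 2.14 ± 0.34 and Srf by 2.08 ± 0.28 (adjusted p = 6.37e-17), and of 29 early estrogen genes 9 rose and 1 fell, Vegfa by 2.30 ± 0.46 (adjusted p = 2.19e-05). MAPK feedback genes rose in 7 of 19 cases, Dusp6 by 1.81 ± 0.39 (adjusted p = 1.06e-05, adjusted p = 0.0515 with an estimated correlation). Ribosome biogenesis genes rose in 14 of 29, Ddx21 by 2.32 ± 0.42 (adjusted p = 1.35e-15, adjusted p = 0.202 with an estimated correlation). Chemokines and cytokines rose in 5 of 34 cases and fell in 1, Ccl2 by 2.65 ± 0.62 and Ccl7 by 2.52 ± 0.46 (adjusted p = 8.79e-05, adjusted p = 0.661 with an estimated correlation). Of 24 FoxO targets, 4 fell and 2 rose, Fbxo32 by -3.24 ± 0.81 (adjusted p = 0.048, adjusted p = 0.723 with an estimated correlation). Over each list alone, 17 immediate early, 13 early estrogen, 8 MAPK feedback and 22 ribosome biogenesis genes were higher.

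The comparison of IGF1 at 2 h with vehicle in KO called 2150 genes, 1262 higher and 888 lower, with 434 and 200 at least 2-fold. The count was 310 without KO IGF1 2 h replicate 1, 898 without replicate 2, 3900 without replicate 3, 1302 without KO vehicle replicate 1, 1224 without KO vehicle replicate 2 and 0 with only the compared groups in the fit. Quantile normalization moved the higher share from 58.7% to 47.2% and centring to 69.6%. On the arrays of this group the median change of the genes that rose at least 2-fold in WT was 1.28, 0.97 and 0.33, the last on replicate 3.

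The corresponding question at 24 h was what 3 injections of IGF1 changed in KO. S100a8, a neutrophil gene, rose by 6.18 ± 1.63 (adjusted p = 0.012), Lgals1 by 3.95 ± 0.53 (15.5-fold), Igfbp5 by 3.89 ± 0.55, the acute phase gene Serpina3n by 3.54 ± 0.90 and the proteoglycan gene Vcan by 3.52 ± 0.34. Lrp2 (3.01 ± 0.43), Hdc (2.93 ± 0.47) and Atp5mpl (2.89 ± 0.44), of the mitochondrial ATP synthase, rose too. Hpgds fell by 5.98 ± 0.43 (63.2-fold, adjusted p = 2.12e-08), Inmt by 4.66 ± 0.96, Speer8-ps1 by 3.80 ± 0.60, Coch by 3.62 ± 0.46, Galnt15 by 3.52 ± 0.64, Lepr by 3.48 ± 0.46, Abca6 by 3.34 ± 0.46 and Speer4e by 3.05 ± 0.49 (at least 6.09-fold). Igf1r fell by 1.65 ± 0.33.

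Genes of the oxidative phosphorylation list rose in 18 of 24 cases in that comparison, the citrate synthase gene Cs by 2.33 ± 0.52 and Cox5a by 2.30 ± 0.45 (adjusted p = 3.67e-14, adjusted p = 0.332 with an estimated correlation). DNA replication genes rose in 14 of 29, Mcm5 by 1.06 ± 0.15 (adjusted p = 1.04e-08, adjusted p = 0.332 with an estimated correlation), and mitosis genes in 10 of 28, Mki67 by 2.10 ± 0.59 (adjusted p = 1.3e-06, adjusted p = 0.61 with an estimated correlation). ER chaperones rose in 13 of 22, Calr by 1.96 ± 0.29 (adjusted p = 1.99e-08, adjusted p = 0.332 with an estimated correlation). Of 30 collagens and matrix genes, 15 rose and 1 fell, Fn1 by 2.49 ± 0.48 (adjusted p = 9.31e-07, adjusted p = 0.332 with an estimated correlation). Of 12 stroma markers, 6 rose and 1 fell, Vim by 1.52 ± 0.30 and Dcn by -2.20 ± 0.30 (adjusted p = 0.000189, adjusted p = 0.354 with an estimated correlation). Of 20 genes of the progesterone and hedgehog axis, 9 rose and 1 fell, Alox15 by 2.40 ± 0.46 (adjusted p = 0.000534, adjusted p = 0.332 with an estimated correlation). Cholesterol synthesis genes rose in 7 of 18, Fdps by 1.79 ± 0.36 (adjusted p = 1.79e-05, adjusted p = 0.51 with an estimated correlation), and 5 of 24 FoxO targets fell, Txnip by 1.89 ± 0.44 (adjusted p = 0.000388, adjusted p = 0.527 with an estimated correlation). Adjusted over each list alone, 21 oxidative phosphorylation, 18 replication, 17 mitosis, 16 ER and 17 matrix genes were higher. In all 4107 genes were called, 2796 higher and 1311 lower, with 1125 and 326 at least 2-fold. The count was 2644 without KO IGF1 24 h replicate 3 and 2544 without KO vehicle replicate 2, and quantile normalization moved the higher share from 68.1% to 52.9%.

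Whether IGF1 acted differently in KO and WT was tested in the same way as for E2. At 2 h 4 genes were called, Trim45 (1.47 ± 0.25, adjusted p = 0.0469) and Slc7a15 (1.17 ± 0.19) with a positive difference and the G protein gene Gna14 (-1.49 ± 0.24) and Creb3l1 (-1.99 ± 0.33), a secretory pathway transcription factor gene, with a negative one. For Slc7a15 3 of the 4 groups lay at background. At 24 h 2 genes were called, both negative, 1 of them Hpgds at -4.51 ± 0.61 (adjusted p = 0.00394). At unadjusted p < 0.05 there were 2071 genes at 2 h and 2019 at 24 h. No member of any list was called: cholesterol synthesis at 2 h gave adjusted p = 8.82e-12 (adjusted p = 0.467 with an estimated correlation) with 5 genes lower when adjusted over the list alone, and interferon genes at 24 h adjusted p = 7.74e-09 (adjusted p = 0.93 with an estimated correlation) with 5 higher. Ribosome biogenesis at 2 h had a median of -0.44 (camera adjusted p = 2.89e-12, adjusted p = 0.467 with an estimated correlation). ER chaperones at 2 h had -0.57 (adjusted p = 1.98e-08, adjusted p = 0.467 with an estimated correlation). Mitosis genes at 24 h had -0.45 (adjusted p = 1.07e-06, adjusted p = 0.93 with an estimated correlation). Replication genes at 24 h had -0.20 (adjusted p = 0.00262, adjusted p = 0.93 with an estimated correlation). At 2 h the count was 0 without any 1 of KO vehicle replicates 1, 2 and 3, WT IGF1 2 h replicates 1 and 3 or WT vehicle replicate 3. It was 8 without KO IGF1 2 h replicate 1, 1 without replicate 3, 2 without WT vehicle replicate 2, 0 with only the compared groups in the fit, 0 with quantile normalization, 7 with dim genes removed and 8 with array weights. At 24 h it was 9 without KO IGF1 24 h replicate 2, 5 without WT vehicle replicate 2, 18 with array weights and 1 with a replicate block, with either rescaling or without the arrays of lowest weight. A difference that was not called does not show that the genotypes acted alike.

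The genes that changed at least 2-fold in WT were followed in KO without a further test. For the 1158 genes higher with E2 at 2 h, the median was 1.42 in WT and 0.16 in KO, with 23 called in KO, and for the 744 lower genes -1.28 and -0.17. For the 2391 genes higher with E2 at 24 h the medians were 1.53 and -0.04, with 0 called in KO, and for the 816 lower -1.31 and 0.04. For IGF1 at 2 h the 979 higher genes had medians of 1.35 in WT and 0.87 in KO, 98.7% of them in the same direction and 578 called, and the 570 lower -1.27 and -0.79 with 268 called. These KO calls depend on the fit and on single arrays. The comparison of IGF1 at 2 h with vehicle in KO had 0 genes called with only the compared groups in the fit, 310 without KO IGF1 2 h replicate 1 and 3900 without replicate 3. For IGF1 at 24 h the 495 higher genes had medians of 1.29 and 1.38, 99.8% in the same direction and 411 called, and the 59 lower -1.31 and -1.03 with 37 called.

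The next question was how E2 and IGF1 differed in WT. The 2 h groups had 1 injection each, but at 24 h E2 had been given once and IGF1 3 times, the last time at 16 h, so the 24 h contrasts also hold the number and timing of injections. At 2 h Klk1 (8.74 ± 0.36, 427-fold), Mad2l1 (6.94 ± 0.27), Klk1b5 (6.24 ± 0.22, at least 37.8-fold) and Pgf (5.81 ± 0.16) were higher with E2, as were Greb1 (4.80 ± 0.14), Igf1 (2.71 ± 0.28) and Pgr (2.54 ± 0.33). Cd248 (-5.30 ± 0.54), Ptch1 (-2.93 ± 0.47), the Wnt antagonist gene Nkd2 (-2.87 ± 0.21) and Lsp1 (-2.78 ± 0.28) were higher with IGF1. Of 29 early estrogen genes, 14 were higher with E2 and 2 lower (adjusted p = 2.87e-16). Of 18 cholesterol synthesis genes, 12 were lower with E2 (adjusted p = 3.79e-13, adjusted p = 0.111 with an estimated correlation), as were 8 of 20 progesterone and hedgehog axis genes with 1 higher (adjusted p = 3.18e-06), 8 of 37 Wnt signalling genes with 2 higher (adjusted p = 0.000389) and 6 of 12 stroma markers (adjusted p = 2.96e-09). At 2 h 1679 genes were called, 844 higher and 835 lower with E2, and 3893 with array weights.

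At 24 h in WT, Sprr2f (9.70 ± 1.55), Sprr2b (8.25 ± 1.24), Sprr1a (7.17 ± 1.12) and Klk1 (6.55 ± 0.36, at least 75.6-fold) were higher with E2 than with IGF1. Tgfbi (-4.43 ± 0.51), Stc1 (-3.67 ± 0.48), Igfbp3 (-3.03 ± 0.49) and the dendritic cell gene Cd83 (-2.22 ± 0.43) were lower. All 28 mitosis genes were higher with E2 (adjusted p = 2.76e-39), Ube2c by 3.66 ± 0.53, as were 27 of 29 replication genes (adjusted p = 6.87e-37), all 18 cholesterol synthesis genes (adjusted p = 2.23e-25), 24 of 29 ribosome biogenesis genes (adjusted p = 1.72e-25) and 16 of 24 late estrogen genes (adjusted p = 9.63e-20). In all 3037 genes were called, 2287 higher and 750 lower. The count was 1583 without WT IGF1 24 h replicate 2, 1880 without WT E2 24 h replicate 2, 1946 without WT E2 24 h replicate 3 and 5495 with array weights, and quantile normalization moved the higher share from 75.3% to 65.1%.

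Genes at least 2-fold changed by both treatments in WT were counted as well. At 2 h 534 genes were higher with both, 37.6 by independence, and 373 lower with both, 14.1 by independence. At 24 h 470 of the 495 genes higher with IGF1 were higher with E2 (39.3 by independence), and 51 of 59 lower. These pairs share a vehicle group, and in simulated unchanged genes that alone gave r = 0.498 against 0.712 measured at 2 h. The simulation gave every group the same spread. The WT vehicle arrays had median deviations from their group of 0.233, 0.142 and 0.129, against 0.084 to 0.089 with E2 at 2 h. With IGF1 at 2 h the arrays had 0.086 to 0.102. A noisier shared vehicle raises r in unchanged genes, so the comparison of r cannot show a shared response. Without a shared vehicle, 229 of the 434 genes higher with IGF1 at 2 h in KO were higher with E2 at 2 h in WT (16.7 by independence), and 836 of 1125 at 24 h (89.2 by independence). Both 2 h contrasts still compare with vehicle arrays taken at 24 h, so the difference in time after injection can add to their overlap. Of 48 genes higher with E2 at 2 h in KO, 21 were also higher with IGF1 at 2 h in WT (1.56 by independence).

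In KO the contrast between E2 and IGF1 at 2 h gave Fbxo32 (4.24 ± 0.81), Aox3 (2.38 ± 0.52), Speer8-ps1 (2.33 ± 0.60) and Fbxl20 (1.99 ± 0.41) higher with E2. Spry4 (-3.76 ± 0.65), Thbs1 (-3.51 ± 0.44), Tnfrsf12a (-3.30 ± 0.57) and Ccl12 (-2.91 ± 0.50) were higher with IGF1. Of 25 immediate early genes, 9 were lower with E2 (adjusted p = 1.12e-15), as were 6 of 19 MAPK feedback genes (adjusted p = 3.04e-08) and 14 of 29 ribosome biogenesis genes (adjusted p = 9.39e-19, adjusted p = 0.106 with an estimated correlation), while 7 of 24 FoxO targets were higher (adjusted p = 6.4e-12, adjusted p = 0.106 with an estimated correlation). At 2 h 916 genes were called, 343 higher and 573 lower. The count was 34, 41 and 2922 without KO IGF1 2 h replicates 1, 2 and 3, 423, 373 and 518 without KO E2 2 h replicates 1, 2 and 3, and 0 with only the compared groups in the fit.

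At 24 h in KO, Hpgds (5.67 ± 0.43), Inmt (3.58 ± 0.96), Speer8-ps1 (3.42 ± 0.60) and Speer4e (3.24 ± 0.49, at least 6.91-fold) were higher with E2 than with IGF1, and Lgals1 (-4.10 ± 0.53), Igfbp5 (-3.91 ± 0.55), Vcan (-3.68 ± 0.34) and Serpina3n (-3.26 ± 0.90) lower. Genes of the oxidative phosphorylation list were lower with E2 in 16 of 24 cases, the citrate synthase gene Cs by -2.99 ± 0.52 (adjusted p = 1.57e-13, adjusted p = 0.208 with an estimated correlation), ER chaperones in 16 of 22, Calr by -2.51 ± 0.29 (adjusted p = 2.67e-12, adjusted p = 0.208 with an estimated correlation), and mitosis genes in 12 of 28, Mki67 by -2.25 ± 0.59 (adjusted p = 9.87e-07, adjusted p = 0.577 with an estimated correlation). In all 6468 genes were called, 3060 higher and 3408 lower, 3305 without KO E2 24 h replicate 2, 3926 and 4205 without KO IGF1 24 h replicates 3 and 2, and 3288 with only the compared groups in the fit. The median over all genes was 0.13, and centring moved the higher share from 47.3% to 26.1%.

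The last question was how KO and WT uteri differed under the same treatment. With E2 at 2 h Ltf (6.11 ± 1.40), Cyp2f2 (5.24 ± 1.48), Prap1 (4.61 ± 1.03) and Rgs2 (4.50 ± 0.48) were higher in KO, and Klk1 (-9.40 ± 0.36, at least 484-fold), Mad2l1 (-7.55 ± 0.27), B4galt5 (-6.49 ± 0.35) and Klk1b5 (-6.43 ± 0.22, at least 38.1-fold) lower, among 5388 genes called. With E2 at 24 h Tgfbi (5.93 ± 0.51), Stc1 (5.87 ± 0.48), Inmt (5.27 ± 0.96) and Coch (5.22 ± 0.46) were higher, and Sprr2f (-8.16 ± 1.55), Sprr2b (-7.66 ± 1.24), H1f5 (-7.14 ± 0.60, at least 93.5-fold) and Sprr1a (-6.73 ± 1.12) lower, among 14168 called. All 28 mitosis genes were lower in KO there (adjusted p = 1.93e-30, adjusted p = 0.0827 with an estimated correlation). Of these calls 8350 were higher and 5818 lower, the median over all genes was 0.18, and centring moved the higher share from 58.9% to 38.2%. The KO arrays of this contrast had narrower values, with interquartile ranges of 3.19, 2.84 and 3.19 against 3.63, 3.65 and 3.66 in WT. None of these KO arrays had a probe set at the highest deposited value, nor did WT E2 24 h replicate 2. The same KO arrays enter every other contrast with KO given E2 for 24 h. The count was 10352 with quantile normalization and 9769 without KO E2 24 h replicate 2.

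With IGF1 at 2 h Slc13a5 (4.23 ± 0.51), Prap1 (3.98 ± 1.03), Stc1 (3.31 ± 0.48) and Tnnt2 (2.77 ± 0.57) were higher in KO than in WT, and Slc7a11 (-3.67 ± 0.41), the deiodinase gene Dio2 (-3.60 ± 0.43), Rxfp1 (-3.49 ± 0.35) and Cxcl15 (-3.29 ± 0.65) lower. Of 30 collagens and matrix genes, 8 were lower (adjusted p = 1.07e-10, adjusted p = 0.373 with an estimated correlation). The 589 genes called became 956 without KO IGF1 2 h replicate 1, 270 and 335 without WT IGF1 2 h replicates 1 and 3, 925 without the arrays of lowest weight and 24 with only the compared groups in the fit. With IGF1 at 24 h Slc13a5 (4.24 ± 0.51), Efhd1 (3.57 ± 0.31), Hdc (2.79 ± 0.47) and the ion transport regulator gene Fxyd4 (2.53 ± 0.51) were higher, and Rxfp1 (-4.62 ± 0.35), Cxcl15 (-4.25 ± 0.65), Slc7a11 (-3.77 ± 0.41) and Jchain (-3.56 ± 0.53) lower. The 862 genes called there became 352 and 366 without KO IGF1 24 h replicates 1 and 3, 357 and 573 without WT IGF1 24 h replicates 2 and 3, and 2536 with array weights.

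**Figure D3:**
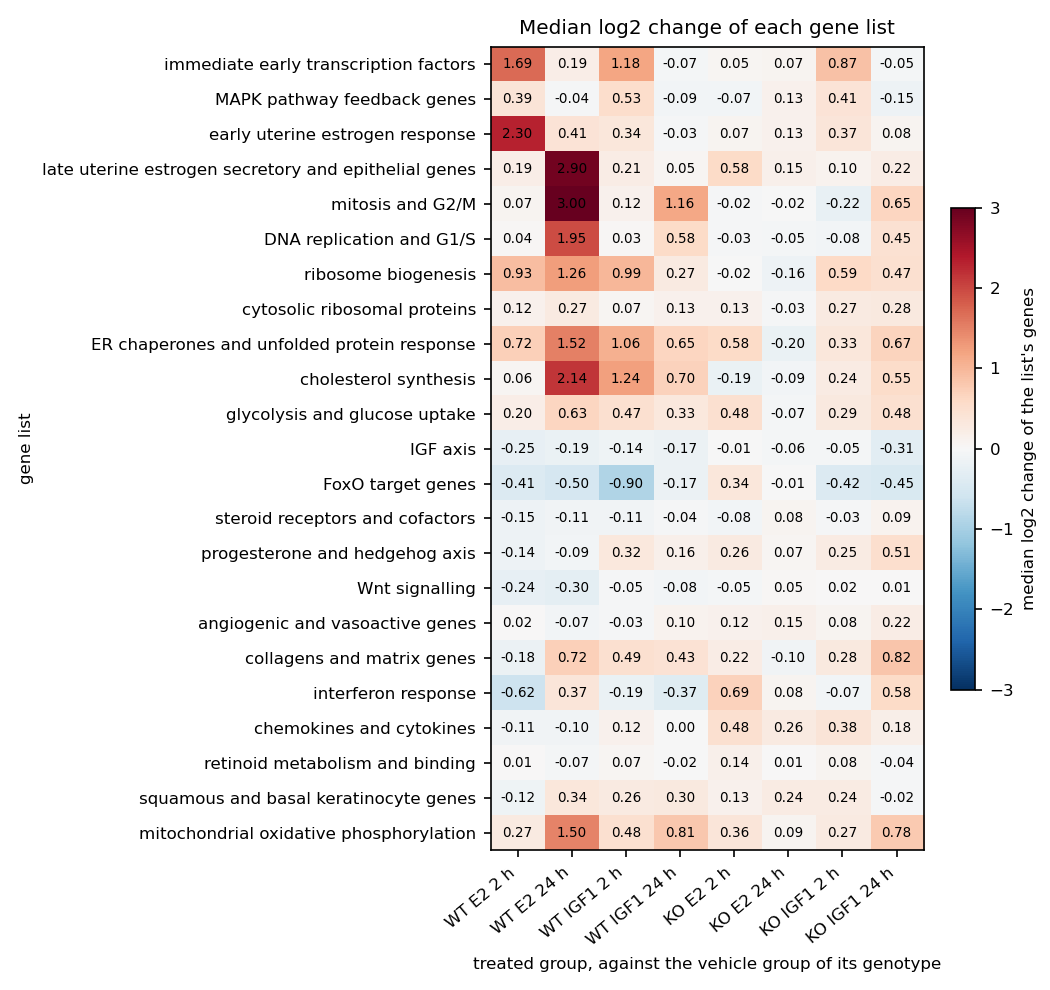
Median log2 change of the members of each of the 23 gene lists (vertical) in each treated group against the vehicle group of its genotype (horizontal), as color. Marker lists are not shown. Mitosis and G2/M genes had a median of 3.00 with E2 at 24 h in WT and 1.16 with IGF1 at 24 h in WT.

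**Figure D4:**
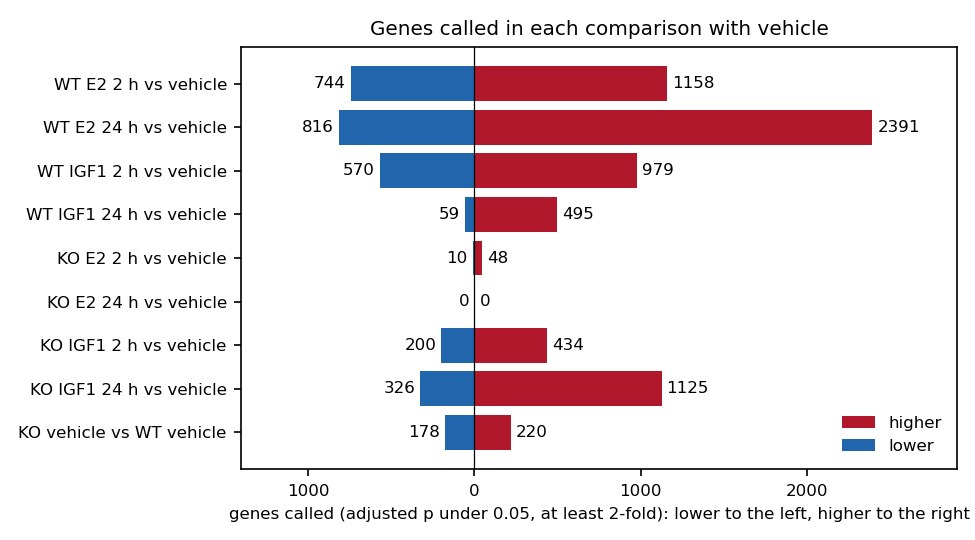
Number of genes called higher and lower at adjusted p < 0.05 and at least 2-fold, as bars, for each treatment against vehicle and for KO against WT vehicle. E2 at 24 h gave 2391 higher and 816 lower genes in WT and 0 in KO.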

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

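The test for male tissue, the test for E2 acting without estrogen receptor alpha and both tests of KO IGF1 2 h replicate 3 were chosen only after the results were seen. For E2 without the receptor, the criterion was also changed after its value was known.

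WT vehicle replicate 1 had Xist at 10.16 against 17.01 to 18.12 on the other 29 arrays. A cell population with a single X chromosome predicts lower genes that escape X inactivation, and their median was -1.02 against the other WT vehicle arrays, which fits. Degraded RNA or a poor array predicts loss of other long nuclear RNAs, and their median was -0.40, which argues against it as the whole cause. The array was still the poorest by weight, 0.166, with Tsix, an RNA antisense to Xist, at -1.49, so a part in it is not excluded. Tissue of a male animal predicts Y-linked RNA, which was only 0.36 above the other arrays and argues against it. Counting X and Y chromosomes in DNA of the same sample would decide between these.

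In KO 110 genes differed between E2 at 2 h and vehicle. An effect of E2 without the receptor cannot be told apart from handling: 89.1% of these genes moved the same way in WT given IGF1 for 2 h, which got no E2, but 15 of them were called between E2 and IGF1 at 2 h in KO. Another time of day cannot be told apart either, the 9 clock genes not looked at before having a median absolute change of 0.36, at percentile 91.9 of random lists. All 16 clock genes measured had 0.55, with 3 called, Arntl (1.38), Npas2 (2.02) and Nfil3 (0.64). These 3 were also called higher at 2 h in WT given E2, WT given IGF1 and KO given IGF1, and in no 24 h group. Dbp was at -3.04, -2.02 and -1.05 in those 2 h groups, and at -1.01, not called, in KO given E2. Per1 was called in no 2 h group and Cry2 (1.32) only in WT given E2. Every 2 h contrast with vehicle thus also holds a shift of some clock genes. Glucocorticoid release after the injection predicts a rise of its target genes, and the 7 set aside as not looked at before had a median change of 1.14, at percentile 100 of random lists, which fits, although none of the 7 was called on its own. The 7 include Cebpd, which also belongs to the early uterine estrogen response list tested earlier. The random lists drew each gene singly, so they do not hold the correlation between genes that move together. All these percentiles can therefore be too high and do not show how rare such a median is. The same 7 had a median of 0.85 in WT given E2 for 2 h, at percentile 99.8 of random lists. Mt2 (1.66) and Pdk4 (3.21) were called there, but Klf9 (0.47) was not and Hif3a (-0.09) did not rise. With IGF1 at 2 h their median was 0.61 in WT (percentile 99.0, 2 called) and 0.83 in KO (percentile 99.96, 3 called). Outside these 7, Tsc22d3 (-0.34), Per1 (0.08) and Zbtb16 (0.82) were not called in WT given E2. Fkbp5, Sgk1, Nfkbia, Map3k6 and Errfi1 were called higher there. A vehicle group taken 2 h after injection would set an effect of E2 apart from handling, but not time of day from glucocorticoid release.

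KO IGF1 2 h replicate 3 was unlike the other 2 of its group. An exchange with a KO E2 2 h array predicts 1 of those scoring near IGF1, and the highest reached 0.356 of the mean of replicates 1 and 2, which argues against it. A weaker or missed exposure cannot be told apart from other causes: the higher of the ratios to the other 2 arrays, for risen and fallen genes, was 0.289, but the array was noticed by these same values. The arrays stood at 1.28, 0.97 and 0.33 for the genes that rose in WT. Phosphorylated IGF1 receptor in the same tissue would test the exposure.

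Arrays were also regrouped. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05, so the real count and the highest other count are given, and except where said 1 split, the real one, called as many genes. For E2 in WT they were 5731 and 0 at 2 h and 9065 and 3 at 24 h, and for IGF1 in WT 5178 and 1 at 2 h and 1291 and 2 at 24 h. In KO they were 110 and 1 for E2 at 2 h, 2150 and 798 for IGF1 at 2 h and 4107 and 0 for IGF1 at 24 h. For E2 at 24 h in KO they were 0 and 139, and all 10 splits called as many. For KO against WT they were 879 and 4 with vehicle, 5388 and 0 with E2 at 2 h, 14168 and 0 with E2 at 24 h, 589 and 106 with IGF1 at 2 h and 862 and 0 with IGF1 at 24 h. Between E2 and IGF1 they were 1679 and 1 at 2 h and 3037 and 1 at 24 h in WT, and 916 and 892 at 2 h and 6468 and 1 at 24 h in KO.

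For the interactions genotypes were exchanged within treatments in 100 splits, a scheme fixed beforehand. As many genes as the real split were called in 9 splits for E2 at 2 h (2412 real, 4286 highest other), 8 for E2 at 24 h (6672, 12911), 17 for IGF1 at 2 h (4, 1737) and 15 for IGF1 at 24 h (2, 1952). These counts include the real split. For E2 all the others among them kept the treated arrays in their genotypes and exchanged vehicle arrays alone, so they hold the true difference between treated KO and WT. Splits that mixed the treated arrays called at most 327 genes at 2 h and 143 at 24 h. For IGF1 such splits called up to 1040 and 459 genes, many times the real counts. Why such splits called more genes than the real one was not tested, and exchanged arrays also carry the difference between the vehicle groups. For IGF1 the count of splits therefore leaves open whether chance can be excluded. For E2 the count cannot decide it, because the splits that reached it hold the true difference of the treated arrays. The E2 splits that mixed the treated arrays stayed far below the real counts.

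Values that differed between the genotypes in the response to E2 at 2 h were Serpinb11 5.43, Rspo3 4.83, Rgs2 4.71, Acod1 4.14, Cldn1 3.71, Sesn1 3.69, Sox4 3.49 and Pigr 3.42, and Adamts4 -5.52, B4galt5 -5.62, Pgf -5.91, Gadd45g -6.11, Klk1b5 -6.30, Ccn1 -6.34, Mad2l1 -7.53 and Klk1 -9.50. In the response to E2 at 24 h they were Cdr1 4.23, Pamr1 3.57, Igfbp3 3.55, Tgfbi 3.22, Apod 3.22, Abi3bp 3.13, Speer8-ps1 3.08 and Abca8a 3.03, and Klk1 -5.95, Ube2c -6.01, H1f5 -6.11, Adgrg7 -6.25, Clca1 -6.35, Sprr1a -7.17, Sprr2b -8.07 and Sprr2f -8.91. For IGF1 they were Trim45 1.47, Slc7a15 1.17, Gna14 -1.49 and Creb3l1 -1.99 at 2 h and Hpgds -4.51 at 24 h. The sizes are uncertain where some of the 4 groups lay at background: at 2 h 3 for Acod1, Adamts4, Klk1b5 and Slc7a15, 2 for Klk1 and 1 for Gadd45g, and at 24 h 2 for Adgrg7 and 1 for Klk1, H1f5 and Sprr1a.

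List medians of the interaction for E2 at 2 h were -1.60 for immediate early transcription factors, -1.35 for the early uterine estrogen response, -1.01 for ribosome biogenesis and 1.41 for uterine stroma markers. At 24 h they were -2.98 for mitosis and G2/M, -2.01 for DNA replication and G1/S, -1.355 for ribosome biogenesis, -1.59 for ER chaperones, -2.19 for cholesterol synthesis, -0.78 for collagens and matrix genes, -1.48 for oxidative phosphorylation and -2.56 for uterine epithelium markers.

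Of 42084 probe sets without a single gene name, 5585 were called for E2 at 2 h and 8989 at 24 h in WT, 3417 for IGF1 at 2 h and 155 at 24 h in WT, 9 for E2 at 2 h and 8 at 24 h in KO, 903 for IGF1 at 2 h and 3158 at 24 h in KO, and 374 for KO against WT vehicle.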

How the results depend on the processing

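The setting without the 2 arrays of lowest weight was chosen only after the results were seen.

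With only the compared groups in the fit, the interactions called 4046 genes for E2 at 24 h and 0 for IGF1 at 2 h, KO E2 at 2 h 7, KO IGF1 at 2 h 0, KO against WT vehicle 211, KO against WT with IGF1 at 2 h 24, WT IGF1 3338 at 2 h and 136 at 24 h, and E2 against IGF1 in KO 0 at 2 h and 3288 at 24 h. With array weights the interactions called 4626 genes for E2 at 2 h, 8 for IGF1 at 2 h and 18 for IGF1 at 24 h, KO against WT 2444 with vehicle and 2536 with IGF1 at 24 h, WT E2 at 2 h 9266, WT IGF1 8595 at 2 h and 3946 at 24 h, and E2 against IGF1 in WT 3893 at 2 h and 5495 at 24 h. Without the 2 arrays of lowest weight, the interactions called 4061 genes for E2 at 24 h and 1 for IGF1 at 24 h, KO E2 at 2 h 235, KO against WT with IGF1 at 2 h 925 and WT IGF1 at 24 h 728. The interaction for IGF1 at 24 h called 1 gene with centred arrays, 1 with quantile normalization and 1 with a replicate block, that for IGF1 at 2 h 0 with quantile normalization and 7 with dim genes removed, and KO E2 at 24 h 1 with centred arrays and 1 with quantile normalization. Replicate numbers did not pair arrays over all groups together, the median correlation of the residuals of 135 pairs of equal number being 0.0078. Of these pairs 28 were over 0.1, the highest at 0.43, against 45 of 270 pairs of different number. Pairing between some groups is not excluded.

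Under quantile normalization the median of the 13 measured of 31 planned cytosolic ribosomal proteins turned direction in 6 comparisons. It went from 0.27 to -0.105 for cytosolic ribosomal proteins, WT E2 24h vs WT vehicle. It became 0.081 for the interaction with E2 at 24 h, 0.0035 for KO against WT with E2 at 24 h, 0.13 for E2 against IGF1 at 24 h in KO, -0.12 for KO IGF1 at 24 h and -0.087 for WT IGF1 at 24 h. With each array left out, the median of the FoxO targets in the interaction for IGF1 at 2 h ran from 0.0067 to 0.60, lowest without KO IGF1 2 h replicate 3, where the list test turned direction.

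Without a fold limit, genes called in the same direction in WT E2 2h vs WT vehicle and WT IGF1 2h vs WT vehicle were 3375 instead of 907. Those called in WT at 24 h were 1221 instead of 521, and in KO at 2 h 58 instead of 25. With the KO response to IGF1 in place of that of WT, and at least 2-fold, they were 349 at 2 h, and 1007 in place of genes called in the same direction in WT E2 24h vs WT vehicle and WT IGF1 24h vs WT vehicle. In KO the genes that IGF1 changed in WT at least 4-fold at adjusted p < 0.01 were followed as well. Their KO median at 2 h was 1.68 for 124 higher genes and -1.59 for 67 lower genes. At 24 h the median was 1.99 for 16 higher genes and -2.95 for only 3 lower genes. It was -0.13 for genes lower with E2 at 24 h, and without a fold limit 0.97 and -0.44 for IGF1 at 24 h. The cause was not tested.

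With each array left out in turn, counts ran from 4303 to 5503 for WT E2 at 2 h, 6943 to 9335 at 24 h, 3748 to 5126 for WT IGF1 at 2 h, 278 to 1343 at 24 h, 28 to 332 for KO E2 at 2 h, 0 to 38 at 24 h, 310 to 3900 for KO IGF1 at 2 h, 2544 to 3591 at 24 h and 470 to 844 for KO against WT vehicle. Interactions ran from 1665 to 2487 for E2 at 2 h, 4555 to 7733 at 24 h, 0 to 8 for IGF1 at 2 h and 1 to 9 at 24 h. E2 against IGF1 ran from 1178 to 1340 at 2 h and 1583 to 2626 at 24 h in WT, and 34 to 2922 and 3305 to 6423 in KO. KO against WT ran from 3988 to 4655 and 9769 to 13730 with E2 at 2 h and 24 h, and 270 to 956 and 352 to 860 with IGF1.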

Other observations

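The gene families here were chosen only after the results were seen. All 11 measured tissue kallikrein genes, serine proteases of a single cluster, were higher in WT with E2 at 2 h and at 24 h, with medians of 2.10 and 1.21. Klk1b24 rose by 3.85 ± 0.19 and Klk1b21 by 3.70 ± 0.16 at 2 h, and none of the family was called with IGF1 or in KO. The interaction was negative for all 11 with E2 at 2 h, with a median of -2.21, and for 7 at 24 h, with a median of -0.85. These genes are close in sequence and may share probes, so the 11 are not separate observations. The large rise of Klk1 may add to the signal of the others. Of 12 small proline-rich genes, 8 rose with E2 at 24 h in WT, Sprr2g by 3.71 ± 0.56, and 0 with IGF1 at 24 h. Of 12 mucin genes, 3 rose and 3 fell in the same comparison, with Muc20 higher by 4.69 ± 0.36 and Muc4 by 4.48 ± 0.48.

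The families below were not tested against other genes. Of 38 proteasome subunit genes, 34 rose with E2 at 24 h in WT, Psmc5 by 2.75 ± 0.34, 28 with IGF1 at 24 h in KO, Psmb3 by 2.09 ± 0.37, and 12 with IGF1 at 24 h in WT. Of 72 mitochondrial ribosomal protein genes 65, 51 and 7 rose there, Mrpl42 by 2.42 ± 0.29 with E2 in WT and Mrpl52 by 2.06 ± 0.31 with IGF1 in KO. The interaction for IGF1 at 24 h had medians of 0.27 and 0.29, and no gene of either family was called. Cytosolic aminoacyl-tRNA synthetase genes, which charge tRNA with amino acids, rose in 12 of 15 cases with IGF1 at 2 h in WT, Tars by 2.61 ± 0.43, and in 8 of 15 in KO. Of 7 guanylate-binding protein genes 4 had a positive interaction for E2 at 2 h, Gbp7 by 2.98 ± 0.75.

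As a hypothesis, part of the 2 h changes in KO could be a glucocorticoid response to the injection. The 7 glucocorticoid-induced genes set aside for the test above had a median change of 1.14 with E2, with none of them called on its own. In WT given E2 for 2 h their median was 0.85 with 2 called, but Hif3a (-0.09) among them did not rise. The classic target Tsc22d3 (-0.34), which is not among the 7, did not rise there either. With IGF1 at 2 h the median of the 7 was 0.83 in KO with 3 called and 0.61 in WT with 2 called. Plasma corticosterone and a vehicle group at 2 h, or the same injections after adrenalectomy, would test it.

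A further hypothesis is that the IGF1 program of the uterus may not need estrogen receptor alpha: the 16 genes IGF1 raised in WT at 24 h at adjusted p < 0.01 and at least 4-fold had a median of 2.34 in WT and 1.99 in KO, the KO arrays at 1.39, 2.92 and 1.78. At 2 h the 124 genes raised that much had medians of 2.35 and 1.68, the KO arrays at 2.38, 1.95 and 0.54, and the 67 lowered -2.32 and -1.59, the KO arrays at -2.09, -2.31 and -0.15. The smaller KO medians at 2 h come mostly from replicate 3. All these genes were chosen for large changes in WT, which favours higher values there. Some lists rose less in KO. The interaction for IGF1 at 24 h had a median of -0.45 for mitosis genes (camera adjusted p = 1.07e-06, adjusted p = 0.93 with an estimated correlation). These genes rose in 19 of 28 cases in WT and 10 of 28 in KO. Ribosome biogenesis had -0.44 at 2 h but 0.22 at 24 h. Whether the whole program is kept in KO is therefore open. Counting dividing epithelial cells in KO uteri given IGF1, with more animals per group, would test this hypothesis.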
